A study of Mastomys natalensis with 4 samples.

How the data were processed

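Total RNA of gastric mucosa from 4 samples of Mastomys natalensis, 2 after 8 weeks and 2 after 16 weeks of loxtidine, was measured on Affymetrix mouse U74 arrays, per the labels. The table of the series holds the authors' deposited intensity value for each of 12488 probe sets in each sample, on a linear scale with no value below 0. How these intensities were computed from the scans, and whether the arrays were scaled to each other, is not given in the sources used here. The trimmed means of the 4 columns (2% off each end) were 38.6, 42.3, 41.5 and 39.1, within 4.76% of their common mean, so by a rule fixed beforehand the deposited scale was kept. No batch, date or scanner information was used. The labels do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The groups were taken from the labels' descriptions. The labels give no meaning to the replicate numbers 1 and 2, which here only name the samples.

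The probes were designed on mouse sequence and the RNA came from another rodent genus. Mismatches lower the signal of a probe set by an amount that differs between genes, so differences were taken for the same probe set between samples. A dim probe set does not show that the transcript was absent. Intensities of different probe sets were compared to pick a gene's brightest probe set, to group or match probe sets by brightness and to set controls beside tissue probe sets. Brightness there is that of the signal, which mismatches affect, and not the transcript's level. Gene names came from the platform's annotation, which names mouse genes and can be old. Of 12422 probe sets other than controls 10833 had 1 gene symbol, 396 had several and were not named, and 1193 are unnamed here. No genome was used, so no coordinates are given.

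Values below a floor were set to the floor, the median over the 4 arrays of the array's 40th percentile (12.15), and log2 was taken. Probe sets above the floor on at least 2 of the 4 arrays were tested, 7883 in all, representing 5864 genes. The comparison of 16 with 8 weeks used limma (lmFit and eBayes, version 3.58.1, R 4.3.3) with 2-sided moderated tests and Benjamini-Hochberg adjustment over all tested probe sets, with a threshold of 0.05. With 2 against 2 samples an exact permutation test cannot give a 2-sided p below 0.333, so the test rests on limma's pooling of the spread over probe sets. A floored value makes a difference a lower bound. Where both samples of a group lay under the floor, the fold is therefore given as "at least". Control probe sets were left out of the tests. Counts of higher and lower list members are those on the deposited scale: of 442 members 47 changed sign with quantile normalization and 28 with the arrays on a common median, as did the medians of 9 of the 31 lists under either. With a sample left out the medians of 13 lists changed sign and those of 27 changed sign or moved by over 1.5 times, smooth muscle not among them.

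A total of 31 gene lists, of cell types of the stomach and neighbouring tissues and of pathways, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry's main p asks whether a list's genes move, on balance, in a single direction, its mixed p whether they change in either direction, and neither compares the list with other genes. A gene was represented by its brightest tested probe set with 1 symbol. The groups, lists, tests, thresholds, all alternatives but the last 2 and the rule for naming genes were chosen before the data were examined. The rule named up to 12 genes per direction past the threshold, with places left empty given to the genes with the smallest unadjusted p whose groups did not overlap. It also named up to 4 members of each list with the smallest p, and a fixed set of gastric, ECL cell and AP-1 genes. Of that set Slc18a2 and Pgc were not named by the annotation used here, and Hdc, Jun and Ccn2 did not reach the filter. The matrix genes Col4a1 and Dcn and the acinar genes plotted beside the named ones were chosen after their values were seen.

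The scripts were tested on simulated data made from the probe sets' own mean levels, with 200 changed probe sets. The spreads were drawn at random from the distribution limma fitted over all probe sets, not taken from each probe set. For 16 against 8 weeks with 7758 probe sets tested, limma called 0% of the 2-fold, 18% of the 4-fold, 64% of the 8-fold and 76% of the 16-fold changes, and made 4 false calls. With the smooth muscle list shifted by -0.75 camera called it in 20 of 20 runs, and with no shift in 0 of 20. The simulated genes varied independently, so these runs do not show how often correlated genes give a false call. In the data the estimated correlation was 0.11 for smooth muscle and 0.22 for heat shock and ER stress. These estimates, and camera's p with them, rest on 2 residual degrees of freedom, so a list could hardly pass there. The fibroblast list, with an estimated correlation of -0.0016, went from an unadjusted camera p of 0.025 to 0.128. Failing there therefore does not show that correlation between genes made a call, nor that the call is sound. Alternatives were quantile normalization, a common median, a lower (5.05) and a higher (26.75) floor, a pseudocount in place of the floor, no filter and a stricter filter, leaving out probe sets marked as shared or reduced, a trended and robust variance, the replicate number as a block, leaving out each sample, the mean of a gene's probe sets, an estimated correlation and fry. Chosen after seeing the data were 2 more, which shifted each array's log2 values to align the 9 bacterial hybridisation controls, first by the median of their levels and then by the median of each control's deviation from its own mean.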

Results

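The gastric mucosa of Mastomys natalensis, an African rodent prone to tumours of the stomach's endocrine cells, was profiled on mouse U74 expression arrays during treatment with loxtidine (spelled loxitidine in the labels), a blocker of the histamine H2 receptor that suppresses acid secretion. Enterochromaffin-like (ECL) cells are the histamine-producing endocrine cells of the acid-secreting mucosa and respond to the hormone gastrin. Total RNA came from 2 samples after 8 weeks, a stage labelled ECL cell hyperplasia, and from 2 samples after 16 weeks, a stage labelled ECL cell neoplasia. Untreated mucosa was not analysed here, so the data describe the step from the 8-week to the 16-week stage and not the response to the drug. Treatment time and lesion stage differed together between the groups, and age, not given in the labels used here, may have differed with them. The median intensity of the arrays was 15.4 and 17.3 at 8 weeks and 19.2 and 18.9 at 16 weeks. Between 55.3% and 62.4% of probe sets lay above the floor intensity of 12.15. The number of arrays limits the precision: all differences given are log2 differences, 16 weeks minus 8 weeks, with a standard error (SE) from n = 2 samples per group.

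The comparison addressed which transcripts and which kinds of cells differed between hyperplastic and neoplastic mucosa. Transcripts of smooth muscle were lower at 16 weeks relative to other genes. The list passed limma's camera test (Benjamini-Hochberg adjusted p = 0.000958 over 31 lists). It did not pass camera with an estimated correlation between genes (adjusted p = 0.756) or the fry test (adjusted p = 0.168). With an estimated correlation camera rests on 2 residual degrees of freedom and passed 0 of the 31 lists, so that failure decides little. Of the 10 tested smooth muscle genes, 8 were lower at 16 weeks and 2 were higher, and the median difference was -0.76, which is 1.69-fold. Smoothelin (Smtn), a cytoskeletal protein of contractile smooth muscle, read 157 and 104 at 8 weeks against 24.1 and 21.2 at 16 weeks, a difference of -2.50 ± 0.30 (SE). Enteric smooth muscle actin (Actg2) read 1786 and 1437 against 849 and 866 (-0.90 ± 0.25), calponin (Cnn1), which binds actin, 309 and 226 against 148 and 151 (-0.82 ± 0.27), and myosin light chain kinase (Mylk), which triggers contraction, 654 and 639 against 403 and 403 (-0.68 ± 0.23). After quantile normalization the list's median was -0.49, with Actg2 at -0.49 and Mylk at -0.36, and the sign of desmin (Des), a muscle filament named here after its value was seen, changed. With the arrays aligned on the bacterial hybridisation controls in 2 ways, both chosen after seeing the data, the median was -0.32 and -0.24, with 8 of 10 genes lower in each. Over all probe sets 0 members passed limma's test and 5 had an unadjusted p under 0.05, while adjusted over the list alone 1 of the 10 passed, Smtn (limma adjusted p = 0.00392).

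The second list to pass was that of heat shock and endoplasmic reticulum (ER) stress, made of chaperones and protein-folding enzymes, which was lower relative to other genes. It passed camera with a Benjamini-Hochberg adjusted p of 0.0332, but not with an estimated correlation (adjusted p = 0.756) or by fry (0.649). Of its 23 tested genes 17 were lower at 16 weeks and 6 were higher, with a median difference of -0.37. The list differed about as much between the 8-week samples. In sample 1 over sample 2 of that group its median log2 ratio was -0.36, with 4 of 23 genes higher. For 16-week sample 2 over sample 1 it was -0.06. Its members with the smallest p were ER and mitochondrial folding proteins. The ER chaperone BiP (Hspa5) read 394 and 727 at 8 weeks against 265 and 235 at 16 weeks (-1.10 ± 0.36). The disulfide isomerases Pdia3 and Pdia6 gave -0.99 ± 0.30 and -0.75 ± 0.24, and the mitochondrial chaperone Hspa9 -0.76 ± 0.30. None of these members passed on its own, over all probe sets or adjusted over the list alone. Camera's adjusted p was 0.148 after quantile normalization, 0.0659 with a lower floor, 0.0720 without shared or reduced probe sets and 0.0754 with the mean of a gene's probe sets. Without 8-week sample 2, 16-week sample 1 or 16-week sample 2 camera's adjusted p was 0.133, 0.0592 and 0.187, with medians of -0.24, -0.34 and -0.36. The list's median was smaller than that of the hybridisation controls, -0.57. With the arrays aligned on these controls, by alternatives chosen after seeing the data, its median was 0.06 and 0.14, with 10 and 9 of 23 genes lower, so a fall in absolute level was not shown. Camera, which compares a list with other genes, gave an adjusted p of 0.0375 and 0.0416 there. A shift of whole arrays can do little to change that comparison.

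**Figure D1:**
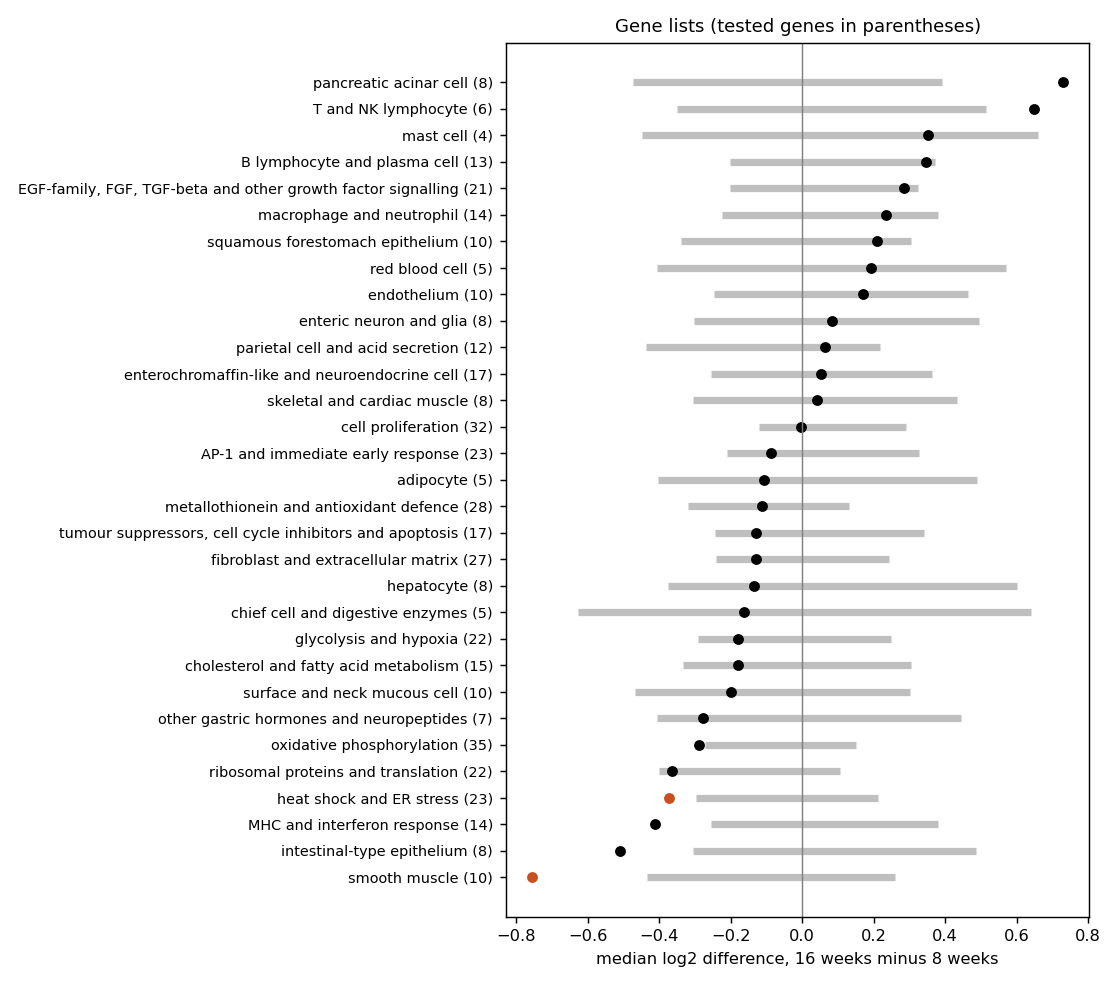
Median log2 difference (horizontal axis, 16 weeks minus 8 weeks) of the tested genes of each of 31 lists, 1 row per list, with grey bars for the central range of 10000 random lists of the same size and brightness. The orange points are the lists that passed camera, smooth muscle at -0.76 and heat shock and ER stress at -0.37. Neither passed camera with an estimated correlation (adjusted p = 0.756 for each), a test on 2 residual degrees of freedom.

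Extracellular matrix and connective tissue genes held both directions. Of 27 tested members 17 were lower and 10 higher at 16 weeks, the median was -0.13, and camera's adjusted p was 0.107. Type III collagen (Col3a1), a fibre of loose connective tissue, read 1949 and 1280 at 8 weeks against 586 and 509 at 16 weeks, a difference of -1.53 ± 0.30. Type V collagen (Col5a2) gave -1.17 ± 0.28 and the PDGF receptor of fibroblasts (Pdgfra) -1.10 ± 0.30 (0.26 on a second probe set), whereas periostin (Postn), a matrix protein secreted by fibroblasts, gave 0.82 ± 0.25. Elastin (Eln), the protein of elastic fibres and the gene with the smallest p of all genes lower at 16 weeks, read 130 and 142 against 29.5 and 30.1 (-2.19 ± 0.23, limma adjusted p = 0.301). Other components of the wall did not pass as lists. The enteric neuron and glia list had 4 of 8 genes lower, a median of 0.08 and a mean of -0.01, with camera's direction down (adjusted p = 0.774). Medians were 0.17 for endothelium, 0.04 for skeletal and cardiac muscle and -0.11 for adipocytes (camera adjusted p = 0.98, 0.514 and 0.506), and 1 skeletal muscle gene, Myh4, was higher with adjustment over the list alone (limma adjusted p = 0.00827). The enteric, skeletal muscle and adipocyte medians changed sign under a scaling alternative. Fry's test for changes in either direction gave an adjusted p of 0.0475 for the adipocyte list.

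**Figure D2:**
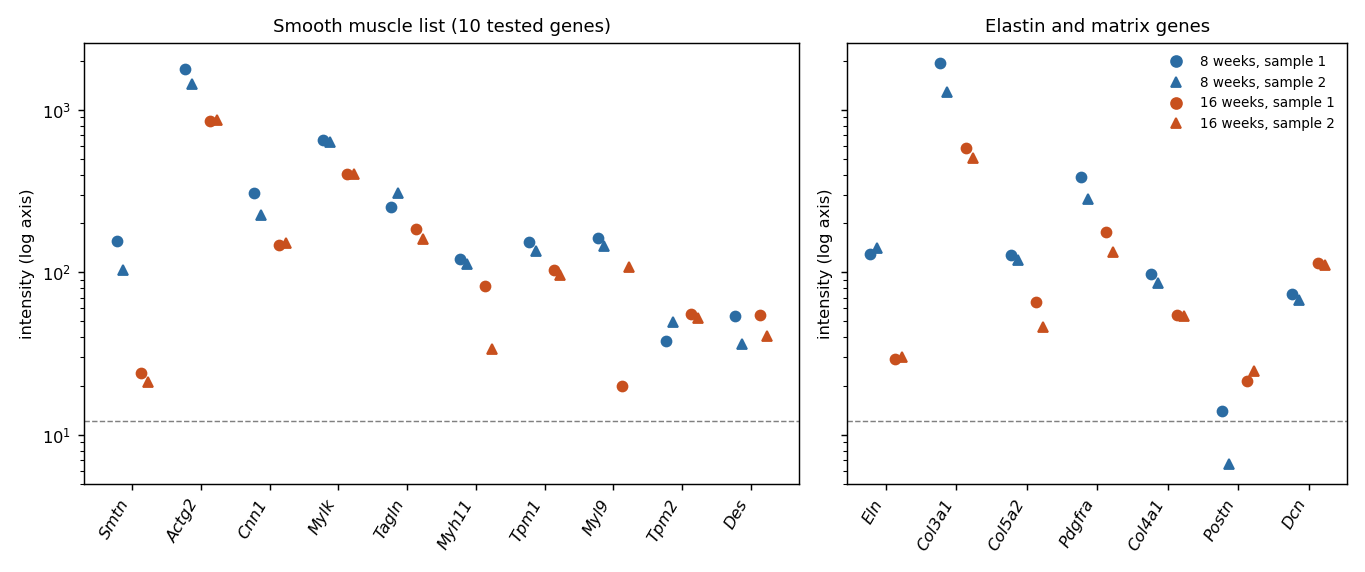
Intensity (vertical log axis) of the 10 tested smooth muscle genes and of elastin and 6 matrix genes in each of the 4 samples, with the floor of 12.15 as a dashed line. Both 16-week samples of Smtn, 24.1 and 21.2, lie below both 8-week samples, 157 and 104.

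ECL cell and neuroendocrine transcripts did not pass as a group. Of 17 tested members 11 were higher and 6 lower at 16 weeks, with a median of 0.05 that became negative after quantile normalization (-0.01) and with the arrays on a common median (-0.07); camera's adjusted p was 0.631. Chromogranin A (Chga), the core protein of endocrine secretory granules, read 141 and 242 at 8 weeks and 299 and 231 at 16 weeks (0.51 ± 0.35), and a second Chga probe set read 42.2 and 70.6 against 142 and 93.7. The gastrin receptor (Cckbr) read 116 and 120 against 151 and 182 (0.49 ± 0.25). Secretogranin II (Scg2) and Snap25, which serve granule formation and exocytosis, gave 0.89 ± 0.31 and 1.06 ± 0.39, and the neuroendocrine hydrolase Uchl1 gave -1.03 ± 0.50. Histidine decarboxylase (Hdc), the enzyme that makes histamine, read 7.8 and 5 at 8 weeks and 7.2 and 4.9 at 16 weeks, below the floor on all 4 arrays, so the mouse probe set gave no measurement of it.

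Gastrin (Gast), the antral hormone that stimulates ECL cells, read 889 and 182 at 8 weeks against 2.7 and 26.8 at 16 weeks, and its 2 other probe sets read 173 and 33.9 against 11.6 and 14.1, and 328 and 170 against 25.8 and 63. All 3 were highest in 8-week sample 1, which also had the highest values of the intestinal-type genes Tff3, Akp3 and Lgals4 given below. The brightest probe set lay under the floor in 1 of the 2 samples at 16 weeks. Its difference was -4.48 ± 0.84, with a limma adjusted p of 0.301 over all probe sets and 0.0129 adjusted over the list alone. The difference was smaller on the 2 other probe sets, -2.55 on each. Substance P precursor (Tac1), a neuropeptide of enteric nerves, read 20.2 and 26.3 against 64.9 and 54.7 (1.37 ± 0.27; limma adjusted p = 0.0129 adjusted over the list alone). Somatostatin (Sst), which restrains gastrin release, gave -0.28 ± 0.23 and galanin (Gal) 0.33 ± 0.26. The list of gastric hormones and neuropeptides had 5 of 7 genes lower, a median of -0.28 (-0.65 to 0.20 with a sample left out) and a camera adjusted p of 0.522, and 1 member higher and 1 lower passed when adjusted over the list alone.

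Acid-secreting and mucus-secreting epithelium did not pass either. The parietal cell list had 7 of 12 genes higher and a median of 0.07 (camera adjusted p = 0.872), although camera's direction was down and the median was negative on a common median (-0.05). The proton pump subunits read 4442 and 5304 against 4850 and 4034 for Atp4a (-0.13 ± 0.26) and 1091 and 1701 against 915 and 634 for Atp4b (-0.84 ± 0.35). Intrinsic factor (Cblif), which binds vitamin B12, gave -0.17 ± 0.29, and both Atp4a and Cblif turned positive after quantile normalization. In the surface and neck mucous list 7 of 10 genes were lower, with a median of -0.20 (0.06 after quantile normalization) and a camera adjusted p of 0.440, and fry's test for changes in either direction gave an adjusted p of 0.0197. Its members went apart: the gastric mucin Muc5ac gave -0.63 ± 0.28, the neck cell trefoil peptide Tff2 -1.09 ± 0.33 and the surface cell peptide Tff1 -0.24 ± 0.23, while keratin 20 (Krt20), a filament of mature surface cells, gave 1.22 ± 0.32 and cathepsin E (Ctse) 0.71 ± 0.32 (-0.13 on a second probe set). The chief cell and digestive enzyme list had 3 of 5 genes lower, a median of -0.16 (0.13 after quantile normalization) and a camera adjusted p of 0.506.

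No list of markers of epithelia from outside the acid-secreting mucosa passed, and such markers differed between samples of one group. Of the intestinal-type list 6 of 8 genes were lower at 16 weeks, with a median of -0.51 and a camera adjusted p of 0.173. The epithelial galectin Lgals4 read 359 and 155 at 8 weeks against 79.5 and 92.5 at 16 weeks. Trefoil factor 3 (Tff3) of goblet cells read 493 in 8-week sample 1 and 17.8, 15.7 and 13.2 in the other samples, and intestinal alkaline phosphatase (Akp3) read 205 in that sample and 8.9, 13.5 and 9.6 in the others. Without 8-week sample 2 the intestinal-type list passed camera (median -0.77, adjusted p = 0.00239), while without 8-week sample 1 its median was -0.17 (0.670). All 8 tested pancreatic acinar genes were higher at 16 weeks, with a median of 0.73 and a camera adjusted p of 0.107, and the list passed camera without 8-week sample 1 (median 1.36, adjusted p = 0.00444) and without 16-week sample 1 (median 1.60, adjusted p = 0.0199), while the median was 0.39 without 8-week sample 2 and 0.35 without 16-week sample 2. Carboxyl ester lipase (Cel), a fat-digesting enzyme, read 1062 and 279 at 8 weeks against 1241 and 1981 at 16 weeks. The squamous forestomach list had 9 of 10 genes higher and a median of 0.21 (camera adjusted p = 0.506), and passed without 16-week sample 1 (median 0.82, adjusted p = 0.00656), while the median was -0.08 without 16-week sample 2. The hepatocyte list had a median of -0.14 and a camera adjusted p of 0.631; prothrombin (F2) was lower and apolipoprotein Apoa2 higher with adjustment over the list alone (limma adjusted p = 0.0405 and 0.0470).

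**Figure D3:**
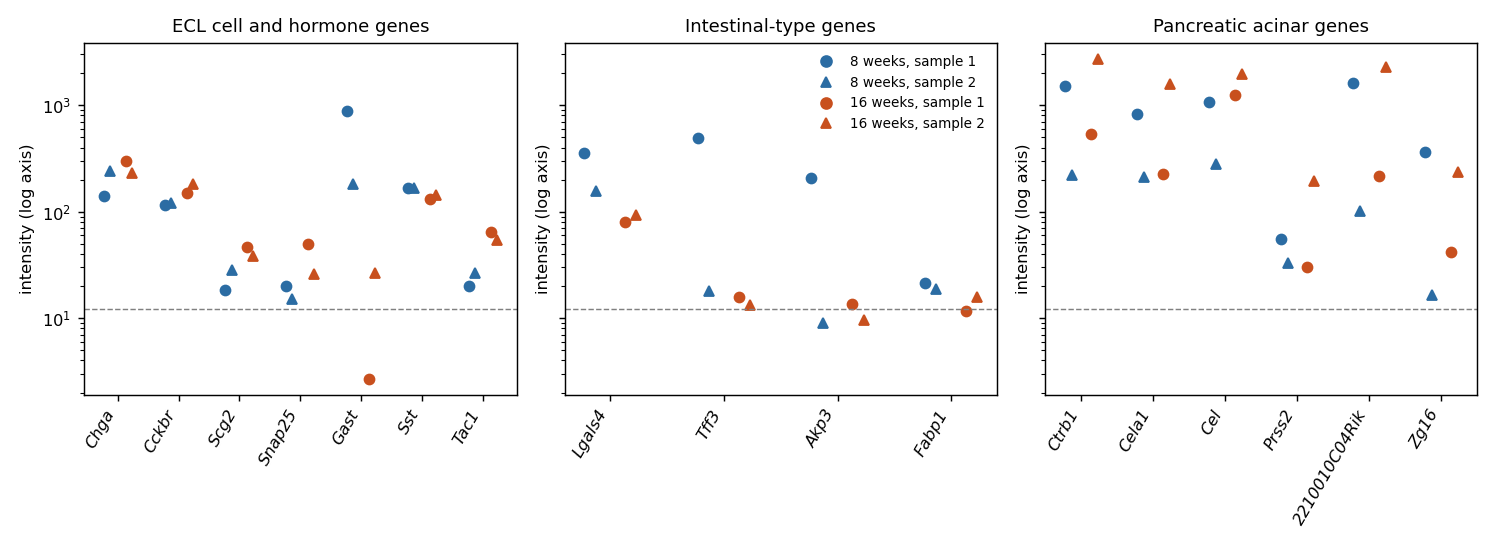
Intensity (vertical log axis) of ECL cell and hormone genes, intestinal-type genes and pancreatic acinar genes in each of the 4 samples, with the floor of 12.15 as a dashed line. Gastrin reads 889 and 182 at 8 weeks and 2.7 and 26.8 at 16 weeks, while Tff3 stands apart in 8-week sample 1 at 493.

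Lymphocyte transcripts lay higher at 16 weeks without passing. All 6 tested T and NK cell genes were higher, with a median of 0.65, and 11 of 13 B cell and plasma cell genes, with a median of 0.35. Camera's adjusted p was 0.107 for both. Dim probe sets in general lay higher at 16 weeks, as given below. The B cell median lay within the central range of brightness-matched random lists (-0.20 to 0.37). The T and NK cell median lay above its range (-0.35 to 0.515). On a common median 1 of the T and NK cell genes, Cd3d (0.07), turned negative. The B cell list passed camera without 8-week sample 1 (adjusted p = 0.0313) and without 16-week sample 1 (0.0308), and the T and NK cell list with a lower floor (0.0218). The helper T cell coreceptor Cd4 read 24.2 and 20.7 at 8 weeks against 42.1 and 54.0 at 16 weeks (1.09 ± 0.26). The cytotoxic protease Gzmb gave 0.96 ± 0.35, with 8-week sample 2 under the floor at 6.1. The B cell kinase Blk gave 1.24 ± 0.43 and the B cell antigen CD20 (Ms4a1) 0.87 ± 0.32. Macrophage and neutrophil, mast cell and red blood cell lists had medians of 0.23, 0.35 and 0.19 (camera adjusted p = 0.506, 0.440 and 0.629). In the MHC and interferon list 10 of 14 genes were lower, with a median of -0.41 (-0.74 to -0.16 with a sample left out) and a camera adjusted p of 0.207. The MHC class II chain H2-Aa read 127 and 36.1 against 19 and 17.4, and its chaperone, the invariant chain Cd74, 42.6 and 36.3 against 22.7 and 15.4. The class II chain H2-Ea lay the other way, at 7.1 and 10 against 25.4 and 20.2, at least 1.86-fold higher.

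Cell division, growth factor and tumour suppressor lists gave no call. The proliferation list was split, with 15 genes higher and 17 lower of 32 and a median of -0.00185 that turned positive after quantile normalization (camera adjusted p = 0.560). Its members with the smallest p were lower at 16 weeks: the chromatin protein Hmgb2 (-1.42 ± 0.30), the mitotic survivin gene Birc5 (-0.96 ± 0.24) and the microtubule regulator Stmn1 (-0.95 ± 0.29). The growth factor list had 15 of 21 genes higher and a median of 0.28 (camera adjusted p = 0.341). Its leading member was Reg3b, a secreted lectin of inflamed epithelium, at 67.7 and 54.0 against 107 and 182 (1.21 ± 0.35, and -0.03 on a second probe set). Tgfa gave 0.28 ± 0.30 and the receptor Fgfr1 -0.77 ± 0.40. Reg1, a gastrin-responsive growth factor, gave -0.18 ± 0.72, from 266 and 74.9 at 8 weeks against 82.2 and 188 at 16 weeks. It was higher in 8-week sample 1 and in 16-week sample 2, as were the pancreatic acinar genes given below. The AP-1 and immediate early list had a median of -0.09 and a mean of 0.05 (camera adjusted p = 0.673), with Fos at -0.57 ± 0.25 and 0.29 on a second probe set and Fosl2 at -0.04 ± 0.33. Jun and connective tissue growth factor (Ccn2) did not reach the filter on dim probe sets. Of the tumour suppressor and apoptosis list, with a median of -0.13 and a camera adjusted p of 0.706, 1 of 17 genes passed adjusted over the list alone. This was the cyclin-dependent kinase inhibitor p19 (Cdkn2d), at 54.1 and 45.4 against 15.4 and 16.9 (-1.62 ± 0.25; limma adjusted p = 0.0196 adjusted over the list alone), while cyclin G1 (Ccng1) gave 0.58 ± 0.24.

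No metabolic list passed. On the deposited scale medians were -0.29 for oxidative phosphorylation and -0.18 for glycolysis and hypoxia (camera adjusted p = 0.107 for both), -0.36 for ribosomal proteins and translation (0.165), -0.18 for cholesterol and fatty acid metabolism (0.506) and -0.11 for metallothionein and antioxidant genes (0.363). After quantile normalization they were -0.09, -0.17, -0.07, 0.03 and -0.01 in the same order, with camera's direction up for the ribosomal and metallothionein lists. The glycolytic enzymes lactate dehydrogenase A (Ldha) and pyruvate kinase (Pkm) read 741 and 590 against 261 and 266, and 681 and 935 against 343 and 263, which is -1.33 ± 0.25 and -1.41 ± 0.30. Respiratory chain subunits Ndufv2 and Cox7a2 gave -0.86 ± 0.25 and -1.06 ± 0.34, and the subunit Cox6b1 gave 0.91 ± 0.33. Among antioxidant genes glutathione reductase (Gsr) gave 1.03 ± 0.27 and peroxiredoxin 2 (Prdx2) -0.82 ± 0.24 (0.17 on a second probe set). The oxidative phosphorylation list passed camera without 8-week sample 1 (adjusted p = 0.0313), without 16-week sample 1 (0.0185) and, with the ribosomal list, at a higher floor (both 0.0304). Its median was -0.11 without 8-week sample 2 (0.383) and -0.09 without 16-week sample 2 (0.405). With a sample left out the median of the glycolysis list lay between -0.42 and -0.03 and that of the cholesterol list between -0.45 and 0.15. The brightest decile of all tested probe sets had a median difference of -0.25, and decile 3, among the dim ones, 0.27. The bacterial hybridisation controls, which do not come from the tissue, had a median of -0.57 over 9 probe sets.

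**Figure D4:**
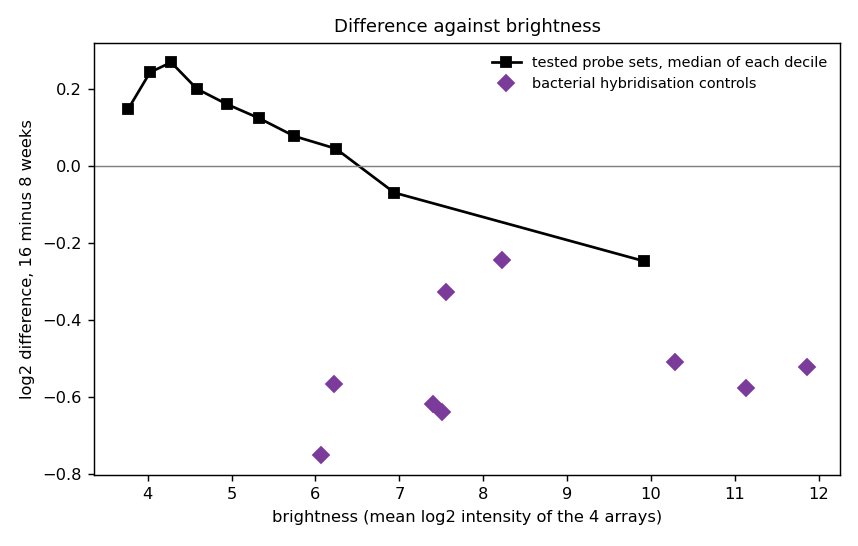
Log2 difference (vertical axis, 16 weeks minus 8 weeks) against brightness (mean log2 intensity of the 4 arrays) for the median of each decile of 7883 tested probe sets and for 9 bacterial hybridisation controls. The medians go from 0.27 in decile 3 to -0.25 in the brightest, and the controls lie between -0.75 and -0.24.

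The rule for naming single genes gave 24, 12 in each direction, with Eln, Smtn and Cdkn2d, given above, among the lower ones. Lipopolysaccharide-binding protein (Lbp) read 12.3 and 16.8 at 8 weeks against 57.9 and 55.1 at 16 weeks (1.97 ± 0.27) and complement C2 read 24.3 and 27.7 against 71.5 and 75.3 (1.5 ± 0.24). Serum amyloid A3 (Saa3) was at least 3.27-fold lower at 16 weeks, where both samples lay under the floor, and the chemoattractant chemerin (Rarres2) read 91.8 and 58.5 against 20.6 and 14.6 (-2.08 ± 0.34). The retinoic acid receptor Rara, a nuclear receptor, read 61.1 and 68.5 against 14.1 and 13.9 (-2.21 ± 0.23). The other genes lower at 16 weeks were Rps4l, Acaa1b, Sbds and Mrpl45, between -2.19 and -1.65, and Babam2 and Stx3, at least 3.16-fold and 2.92-fold lower. Higher at 16 weeks were 1810009J06Rik, from 29.7 and 16.0 to 210 and 327 (3.59 ± 0.41), the ubiquitin protease Usp15 (2.35 ± 0.35, with 1 of the 2 samples at 8 weeks under the floor), the fast skeletal myosin Myh4 (2.01 ± 0.30) and the lipid kinase Pip5k1a (1.46 ± 0.24). Both 8-week samples were under the floor for Atad3a, Uck1, Ankrd46, Sub1, Prss12 and Mpv17, which were at least 4.53-fold, 4.46-fold, 3.79-fold, 3.83-fold, 3.48-fold and 2.79-fold higher. A second probe set of Uck1 and of Sub1 had the opposite sign.

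None of these 24 genes passed the test. Of 7883 tested probe sets 0 were higher and 0 lower at 16 weeks by limma with a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.301. At an unadjusted p under 0.05 limma gave 1100 probe sets, 637 higher and 463 lower, where 394 were expected by chance. The higher and lower counts were 517 and 562 after quantile normalization and 460 and 749 on a common median. With the arrays aligned on the hybridisation controls, as described below, they were 1890 and 96 by median level and 2598 and 76 by median deviation. In 49.3% of tested probe sets the samples of the 2 groups did not overlap, against 33.3% by chance for 2 against 2. In simulated data of this size limma recovered 0% of 2-fold, 18% of 4-fold, 64% of 8-fold and 76% of 16-fold differences, so most 2-fold and 4-fold differences were not detectable with these arrays. Without 8-week sample 1 the unadjusted count was 591. With the arrays aligned on the hybridisation controls the median of all differences moved from 0.09 to 0.52 with the controls' median levels and to 0.60 with the median deviations of each control. Both were chosen after seeing the data, the former first; limma then gave 508 probe sets higher and 29 lower with the former and 0 and 0 with the latter. With the former limma's prior degrees of freedom went from 3.07 to 600, against 5.39 with the latter, so the 537 calls hang on how the controls were averaged and are not used here.

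Agreement between samples of one group overlapped with that between groups. Across tested probe sets, which are not independent replicates, Pearson's correlation of log2 intensity was 0.927 between the 8-week samples, 0.909 between the 16-week samples and 0.865 to 0.915 between groups. The ratio of the 3' to the 5' probe set of beta-actin, a sign of RNA integrity, was 1.26 and 1.16 at 8 weeks and 1.46 and 1.63 at 16 weeks, higher at the stage where the smooth muscle and heat shock lists were lower. For Gapdh it was 0.714 and 0.589 at 8 weeks and 0.891 and 0.647 at 16 weeks.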

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

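The number of lists past the threshold was 2, and 1 with quantile normalization, without the shared or reduced probe sets and with the mean of all probe sets of a gene, 4 with the higher floor and with no filter, 0 with an estimated correlation and 0 by fry, 1 to 5 with a sample left out, and 6 and 3 with the arrays aligned on the hybridisation controls by median level and by median deviation, 2 alternatives chosen after seeing the data. Smooth muscle stayed past it in 15 of 15 alternatives chosen beforehand with camera's preset correlation (adjusted p 0.000135 to 0.0332) and in both control alignments, but not with an estimated correlation (0.756) or by fry (0.168). Heat shock and ER stress stayed in 8 of 15 and in both control alignments (with a median above 0), and camera's adjusted p was 0.148 with quantile normalization, 0.0659 with the lower floor, 0.0720 without shared or reduced probe sets, 0.0754 with the mean of probe sets, 0.00444 to 0.187 with a sample left out (over the threshold without 8-week sample 2 and without each 16-week sample), 0.756 with an estimated correlation and 0.649 by fry; the cause was not tested. The common median and both control alignments shifted all log2 values of an array alike. Camera compares a list with other genes, so these settings could do little to change a call. They are weak support for smooth muscle and for heat shock. The test with an estimated correlation rested on 2 residual degrees of freedom and could hardly pass. Lists that passed only in alternatives with all samples included T and NK cells (0.0218, lower floor), oxidative phosphorylation and ribosomal proteins (both 0.0304, higher floor), and fibroblast and B cell genes (both 0.0295, no filter). With the controls aligned by median level the hormone (0.0235), intestinal-type (0.000346), acinar (0.00135) and MHC (0.0471) lists passed, and by median deviation the intestinal-type list (0.0416). Without 8-week sample 1 the acinar (0.00444), B cell and oxidative phosphorylation (both 0.0313) lists passed, without 8-week sample 2 the intestinal-type list (0.00239), and without 16-week sample 1 the squamous (0.00656), acinar (0.0199), B cell (0.0308) and oxidative phosphorylation (0.0185) lists. By limma 0 probe sets passed in each alternative except 2: with no filter 11 higher and 11 lower did, Tgfbi and Tmem208 among them, from pairs of nearly equal values, and with the controls aligned by median level 508 higher and 29 lower did, where the prior degrees of freedom went from 3.07 to 600 (5.39 by median deviation). The unadjusted count of 1100 went from 591 to 1245 with a sample left out, and was 1986 and 2674 in the control alignments, which moved the median of all differences to 0.52 and 0.60. The share higher among these calls was 57.9%, and 38.1% on a common median, 69.1% with the lower floor and 46.8% with the higher floor. It moved most in the control alignments, to 95.2% by median level and 97.2% by median deviation. A common median moved the median of all differences by -0.12, from 0.09 to -0.03. With the replicate block 987 probe sets had an unadjusted p under 0.05 by limma. No call changed there (camera adjusted p 0.000428 for smooth muscle, 0.0408 for heat shock). Deviations of same-numbered samples correlated at -0.05, which shows no shared effect of the numbers but cannot exclude a pairing. Of 151 named probe sets 134 kept their sign in all alternatives run, and 4 (Atp4a, Cblif, Chia1, Clps) changed it with quantile normalization. Most of these were named for a small p in the same data, which favours a kept sign. Among all 442 list members 47 changed sign with quantile normalization. Only 55.3% to 62.4% of probe sets lay above the floor on an array, and below it no difference can be measured.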

Other observations

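Pancreatic acinar transcripts, markers of enzyme-secreting cells not part of the acid-secreting mucosa, differed between samples of one group. The genes named here for single samples were chosen after their values were seen. Chymotrypsinogen (Ctrb1) read 1514 in 8-week sample 1, 223 in 8-week sample 2, 541 in 16-week sample 1 and 2734 in 16-week sample 2. Elastase 1 (Cela1) read 834, 212, 226 and 1586 in the same order, and the zymogen granule protein Zg16 read 363, 16.5, 41.7 and 234. All 8 tested genes of the list were higher in 8-week sample 1 than in sample 2 and in 16-week sample 2 than in sample 1, with median log2 ratios of 1 and 0.72. Of these 8 genes 0 were in another list. The squamous forestomach genes had 9 of 10 members higher in 16-week sample 2 than in sample 1 (median log2 ratio 0.75), and the intestinal-type genes 7 of 8 members higher in 8-week sample 1 than in sample 2 (0.67).

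Of the tests that follow, those of the muscle wall, of quantile normalization, of the hybridisation controls and of other splits of the samples were chosen after the result was seen. The acinar pattern was tested against a scale difference between arrays: the lower of the 2 percentiles of the list's median among brightness-matched random lists was 100, which a scale difference that acts alike on probe sets of equal brightness does not allow. A second list of acinar genes, written before its values were read, had 9 tested members, and the lower of its 2 median log2 ratios was 0.78, with 6 of 9 members higher in 8-week sample 1 and 7 of 9 in 16-week sample 2. That value is consistent with pancreatic-type acinar cells, as ectopic tissue or as a piece of neighbouring pancreas, in part of the material. Rbpjl, Klk1b5 and Cckar were lower in 8-week sample 1 than in sample 2, colipase (Clps), a pancreatic cofactor counted here with chief cell genes, read 395, 484, 391 and 389, and Pla2g1b, the highest value on each array, cannot show a difference if it was saturated. No biological difference between the samples of one group is given by the labels, so none was tested.

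The lower level of smooth muscle transcripts was weighed against differences in scale and in dissection. Its median had percentile 0 among 10000 brightness-matched random lists, and camera's adjusted p was 0.0332 after quantile normalization. Both argue against a brightness-dependent scale difference as the whole cause. The median went from -0.76 to -0.49 with quantile normalization, so part of the difference goes with the scaling. The list also left the range of such random lists between the 8-week samples, with percentile 99.2 in sample 1 over sample 2. There its median log2 ratio was 0.18, with 8 of 10 genes higher, so the percentile does not tie the difference to the stage. Less muscle wall in the 16-week material may be a cause: the enteric neuron and glia list had a median of 0.0828, but its members went both ways, 4 higher and 4 lower, so this cannot be told apart from a change within the mucosa. A change of the mucosa's own muscle between the labelled stages, and a difference in RNA integrity (actin 3' to 5' ratio 1.26 and 1.16 against 1.46 and 1.63), stay open and untested.

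Bright probe sets were lower and dim probe sets higher at 16 weeks. All 9 bacterial hybridisation control probe sets were lower on both 16-week arrays than on both 8-week arrays, with a median of -0.57. A difference of scale or hybridisation between the arrays would give this. The controls fell at low and high brightness alike: the dimmest, BioB-3, gave -0.75 and the brightest, CreX-3, -0.52. Their fall therefore does not account for dim probe sets lying higher. Tissue probe sets in the controls' brightness range had a median of -0.11 over 2097 probe sets, so they did not shift as much as the controls. A true change in abundant tissue transcripts stays open beside a difference between the arrays.

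The 4 samples allow 3 splits into 2 and 2, too few for a share under 0.05. The real split gave 1100 probe sets with an unadjusted limma p under 0.05, the highest other 251, so 1 of the 3 splits gave a count as large. In each other split both groups held a sample of each stage, so a difference between stages or arrays adds to the spread and lowers the count. Their counts, 251 and 156, lay under the 394 expected by chance, so they do not measure chance.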
